A study of Triticum aestivum with 36 samples.

How the data were processed

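RNA of wheat flag leaves was measured on 36 Affymetrix Wheat Genome arrays, which carry short oligonucleotide probes grouped into probe sets. Per the labels, the arrays form 12 groups of 3, from 3 wheat lines, 2 harvest times (3 and 7 days post inoculation, dpi) and 2 treatments (inoculated or mock). The deposited values are MAS5 signals, an intensity on a linear scale, per the labels; every array had been scaled by the authors to the same median of 500, as the values themselves show. The MAS5 version is not given in the sources used here. Values ran from 0.212 to 470477, and arrays carry no counting depth, so their number limits the precision.

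The deposited data held 61290 probe sets, whose identifiers are written here with _ in place of each point. The 111 AFFX control probe sets were left out, and 64 reporter control probe sets, of which 22 entered the tests, were kept as the design fixed it. Values below the 20th percentile (88.8) were raised to it before taking log2, so a fold change against a group at this floor is a lower bound. A probe set was tested if it exceeded the 40th percentile (313) in at least 3 arrays, which left 48979. No further normalization was applied. Differences were tested with limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8), with a mean for each of the 12 groups and 24 residual degrees of freedom, two-sided, and called at a Benjamini-Hochberg adjusted p under 0.05. The errors printed beside log2 differences are standard errors of that model, and SDs are over the 3 arrays of a group.

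There were 15 comparisons. The 6 responses set inoculated against mock leaves of a line at a time, which is what the series design states. A further 7 set responses against each other, between lines at a time or between times in a line, and 2 set the mock leaves of each resistant line against those of Thatcher over both times. The methods' t-test was run on the same values as an alternative.

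The labels describe a split plot with 3 replicates, separate pots for each, line as the main plot, treatment as the subplot and a mist chamber for each replicate. Replicate numbers therefore pair the mock and inoculated arrays of a line and time. Residuals of paired arrays were positively correlated in 18 of 18 pairs (r across probe sets, 0.151 to 0.679 at 3 dpi and 0.0246 to 0.161 at 7 dpi; 13 exceeded 0.1). The design fixed before the data were examined had no block, so the paired fit (18 pairs as blocks, 12 residual degrees of freedom) is given beside each result that it changes. It gives the same fold changes with other errors, and it cannot give comparisons between mock leaves of different lines.

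Genes were named through the platform's annotation and NCBI RefSeq. A single symbol was given to 1273 probe sets (771 genes, 1272 probe sets matched by Entrez identifier), none had several, and 60017 had none. These tables held no product descriptions, so names other than placeholder identifiers came from RefSeq synonyms, which gave 102 genes a name, with 172 tested probe sets. The rule for named genes, fixed before the data were examined, took up to 12 named genes in each direction per response among called probe sets whose inoculated and mock arrays did not overlap, and the 2 largest changes in each direction whether named or not. For other comparisons it took up to 6 named genes in each direction, and for each gene list up to 3 called members. A gene is shown by its brightest probe set. Where that was not called, the brightest called one is shown with the value of the brightest beside it. Chosen after the data were seen were the use of synonyms, that choice of probe set, the rule applied to calls of the paired fit, and 10 further genes of defence and photosynthesis (PR5, xip, COMT1, PsbO, PsbP, petC, rbcl, PRK, FBP and CAT1).

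Of 22 gene lists fixed before the data were examined, 5 had at least 2 tested genes, 5 had 1 and 12 had none, because few probe sets had names. Lists with at least 2 genes were tested with limma's camera at a preset correlation of 0.01, with 1 probe set per gene, and again with an estimated correlation. Lists extended by abbreviations were added after the data were seen and gave 10 lists with at least 2 tested genes.

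The code was tested on simulated data with the mean and residual SD of each probe set over the 36 arrays (48979 probe sets). Known changes were planted in the inoculated Tc arrays at 7 dpi. Without a block, limma recovered 8.96%, 37.3% and 81.8% of log2 changes of 1, 2 and 3, with 3 false calls, where replicates shared no deviations. With shared deviations of replicate and day added, it recovered 0%, 23.9% and 69.7% without a block, and 0%, 35.8% and 77.3% with the paired block. The residual SD already holds such deviations, which were added again with a common size for all probe sets. These rates therefore need not hold for the real data. The alternatives tried were quantile normalization, scaling to the 75th percentile, no floor, a floor at the 40th percentile, no filter, a filter at the 60th percentile, the replicate number as a block, the paired block, each array left out in turn, limma on the 6 arrays of a comparison alone, the t-test, and every probe set of a gene in the list tests. Chosen after the data were seen were the replicate number within each day as a block, the 6 arrays of replicate 3 at 3 dpi left out together, quantile normalization with the paired block, and the reporter probe sets left out.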

Results

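Flag leaves of 3 near-isogenic wheat lines were compared at anthesis after inoculation with the leaf rust fungus Puccinia triticina, race 1 (BBB), in a light oil, or with the oil alone as mock. Thatcher (Tc) is susceptible to this race. TcLr1 carries the resistance gene Lr1, which acts against particular races, and TcLr34 carries Lr34, which gives partial, race non-specific resistance. Each of the 12 groups had 3 arrays, from separate replicates of the planting. The study asked which transcripts respond to the fungus in each line 3 and 7 days after inoculation (dpi).

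Across the 36 arrays the first principal component held 24.6% of the variance and the second 9.09%. The 6 arrays of replicate 3 at 3 dpi, of all lines and treatments, lay between 125 and 195.1 on the first component, against -110.5 to 44.59 for the other 30. Their polyadenylated spike controls were dimmer (log2 10.32 to 10.71 against 11.73 to 12.72), and their 75th percentiles were lower (1508 to 1757.3 against 1832.2 to 2989). On the second component the inoculated arrays lay below the mock arrays by -70.9 in Tc at 7 dpi, by -32 in TcLr34 at 3 dpi and by -32.1 in TcLr34 at 7 dpi; each exact two-sided permutation p was 0.1, the smallest that 3 arrays against 3 allow. That component also parted TcLr34 from the other lines without inoculation. Mock means at 3 and 7 dpi were -25.17 and -56.74 in TcLr34, 40.57 and 34.41 in Tc, and 45.55 and 33.95 in TcLr1.

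**Figure D1:**
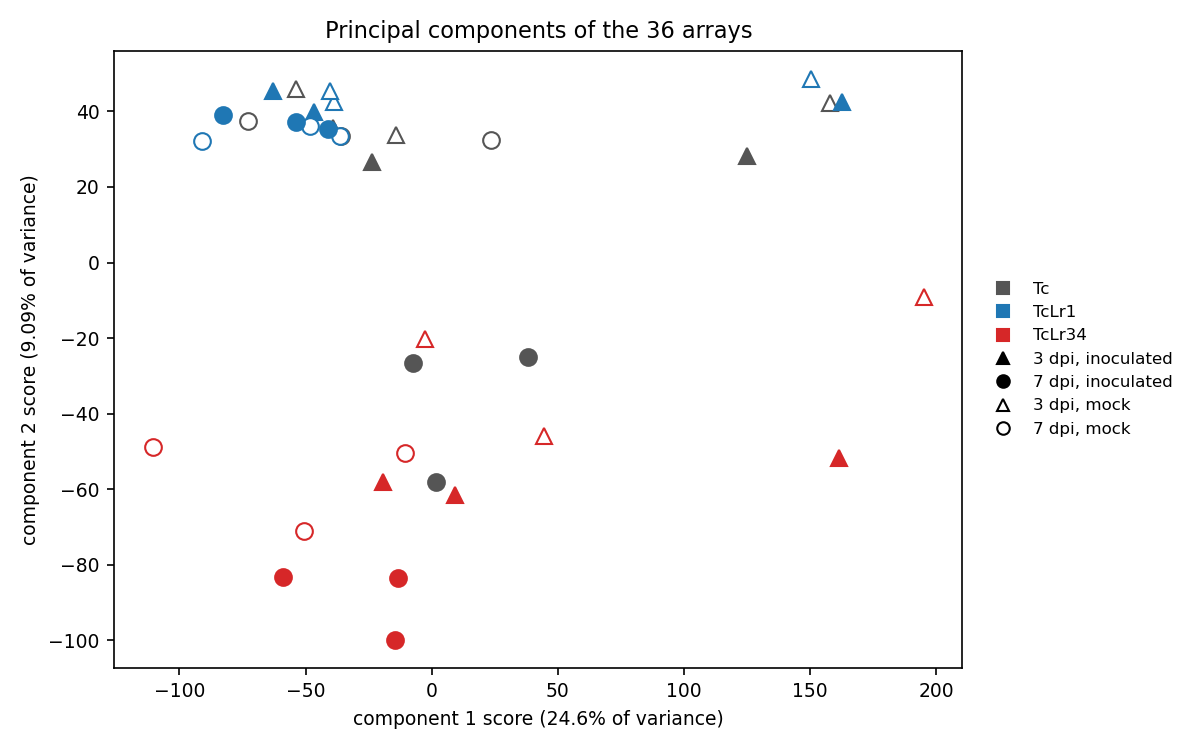
Scores of the 36 arrays on the first (horizontal) and second (vertical) principal components, in score units; colours give the line, triangles 3 dpi, circles 7 dpi, open symbols mock and filled symbols inoculated. The 6 arrays at the right, from 125 to 195.1, are all of replicate 3 at 3 dpi.

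In susceptible Tc at 3 dpi, the response was small and included no named gene. The probe sets Ta_5248_3_S1_a_at (log2 difference 3.91 ± 0.54, adjusted p = 0.00107), Ta_5248_1_S1_x_at (3.38 ± 0.45, 0.000744), Ta_13990_1_S1_at (3.18 ± 0.42, 0.000744), TaAffx_24137_1_S1_at (2.97 ± 0.51, 0.0325) and Ta_5248_2_S1_x_at (2.89 ± 0.52, 0.0476) rose, and all 5 also rose in Tc at 7 dpi. The first went from 6.52 ± 0.08 to 10.43 ± 0.54 (SD, 3 arrays). These 5 were all the calls, named after their values were seen; 0 probe sets fell, where limma gave 1065 at an unadjusted p under 0.05 in both directions against 2449 by chance, and the t-test gave 0 after adjustment and 1072 before. With replicate pairs as blocks 11 rose and 6 fell, including 4 of those 5, and DMAS1, deoxymugineic acid synthase, which makes iron-binding compounds, rose by 1.02 (Ta_5335_1_A1_at, adjusted p = 0.0266; 1 without the block; brightest probe set 0.32, not called). Quantile normalization gave 7 higher and 3 lower. Without inoculated replicate 2 or 3, or mock replicate 1 or 2, 3 calls were made, and none of the gene lists passed. With all arrays of replicate 3 at 3 dpi left out, 1 call was made, and Ta_5248_3_S1_a_at (3.575, adjusted p = 0.215) and Ta_5248_1_S1_x_at (3.25, 0.0589) were not called. The 3'/5' probe ratios of 2 controls differed between the treatments, EF-1 alpha by 1.19 and sucrose synthase by -0.257, each with an exact permutation p of 0.1, the smallest possible here. Several such ratios and other array measures were tried in each response, with no correction for their number. Here and below only those that reached this p are given, and some would reach it by chance.

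In TcLr1 at 3 dpi, TaAffx_21933_1_S1_at rose by 2.94 ± 0.35 (adjusted p = 0.000125) and TaAffx_78959_1_S1_at fell by 2.73 ± 0.41 (adjusted p = 0.0058), neither with a gene name. No other probe set was called by limma, which gave 1335 at an unadjusted p under 0.05. The defence genes PR5, a thaumatin-like protein (0.17), and COMT1, a methyltransferase of lignin synthesis (0.23), were not called. With replicate pairs as blocks 10 rose and 4 fell, and under quantile normalization 10 rose and 2 fell. Without inoculated replicate 2 or 3, 1 call was made, and none of the gene lists passed. The call of TaAffx_78959_1_S1_at was lost without inoculated replicate 2 (-2.61), inoculated replicate 3 (-2.61) or mock replicate 3 (-2.38), and with all arrays of replicate 3 at 3 dpi left out (-2.255, adjusted p = 0.188).

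In TcLr34 at 3 dpi, Rab15, a dehydrin induced by abscisic acid and water deficit, rose by 3.76 ± 0.35 on the log2 scale (TaAffx_46097_2_S1_at, adjusted p = 2.48e-07; 3.26e-06 with replicate pairs as blocks and 6.86e-09 to 0.217 over all alternatives). It was at the floor of 6.47 in all 3 mock arrays and at 10.23 ± 0.63 (SD, 3 arrays) in inoculated leaves, so the change is a lower bound. Groups at the floor have an SD of 0, which lowers the model's error for this probe set in every comparison, so its errors and p-values can be too small. The brightest Rab15 probe set, Ta_2704_1_S1_x_at, differed by 0.97 ± 0.57 and was not called, and another, Ta_2704_1_S1_at, differed by 2.36 ± 0.70 (adjusted p = 0.127; 0.0154 paired; 0.0421 with all arrays of replicate 3 at 3 dpi left out). In all, 454 probe sets rose and 33 fell. Of these, 451 and 33 had inoculated and mock arrays that did not overlap, as had 10.7% of all tested probe sets. That share was 4.63% in Tc and 4.32% in TcLr1 at 3 dpi. Chance gives 10% only for exchangeable arrays without ties, and these arrays are paired, with values tied at the floor. The largest changes were in unnamed TaAffx_108353_1_S1_at (5.98 ± 0.56), TaAffx_83275_1_S1_at (5.67 ± 0.73), TaAffx_81638_2_S1_at (-3.31 ± 0.71) and Ta_13366_3_S1_at (-3.18 ± 0.75). The call of TaAffx_81638_2_S1_at was lost without inoculated replicate 1 (-3.34), inoculated replicate 2 (-3.30) or mock replicate 1 (-2.90). That of Ta_13366_3_S1_at was lost without any 1 array but mock replicate 1 (-3.28 to -3.03) and with all arrays of replicate 3 at 3 dpi left out (-2.94, adjusted p = 0.137). The split depended on the fit: 3219 rose and 1513 fell with replicate pairs as blocks, 1728 and 1243 under quantile normalization, and 1073 and 766 with 75th percentile scaling. Without inoculated replicate 1, inoculated replicate 2 or mock replicate 3 the calls numbered 289, 220 and 292.

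Further named genes of TcLr34 at 3 dpi passed with replicate pairs as blocks and not without them. PR5 rose in that fit by 1.29 (paired adjusted p = 0.00108; 0.472 without the block), xip, a xylanase inhibitor, by 1.47 (0.00475; 0.574) and COMT1 by 0.73 (0.0117; 0.72), while Prx1 of the peroxidase list fell by 0.75 (0.00282), as did 3 of its 4 probe sets. No list test covers these genes together. The zinc finger gene WZF1 rose by 1.30 (paired adjusted p = 0.00366, or 0.462 without the block). The brightest Glc1 probe set rose by 1.21 (0.00916 and 0.259), while its other probe set stood at -0.80, not called. The glyoxalase gene lgul fell by 1.17 (0.00079; 0.0582). Under quantile normalization without a block PR5 (adjusted p = 0.000143), COMT1 (0.000953), lgul (0.00297), Glc1 (0.0243) and Prx1 (0.0405) passed too, and WZF1 (0.0539) and xip (0.0584) did not. With 1 array left out the values ran from 0.85 to 1.81 for PR5, from 0.71 to 2.04 for xip, from 0.39 to 1.006 for COMT1, from 0.76 to 1.64 for WZF1 and from 0.88 to 1.48 for Glc1, each lowest without mock replicate 3. With all arrays of replicate 3 at 3 dpi left out and no block, PR5 was called (1.37, adjusted p = 0.00791), and xip (1.28, 0.134), COMT1 (0.67, 0.308), WZF1 (1.03, 0.188), Glc1 (0.76, 0.557) and lgul (-1.20, 0.0519) were not. Named genes outside photosynthesis were lower with replicate pairs as blocks on all arrays, RPL9 (-0.97) and PEAMT1 (-0.78) among them. Abundant photosynthesis genes were lower in that paired fit too: rbcl, the large Rubisco subunit, by -0.54 (0.0351), and PsbO by -0.54 (0.032) and PsbP by -0.54 (0.0151) of the oxygen-evolving complex. So were petC of the cytochrome complex by -0.55 (0.0156), PRK, phosphoribulokinase, by -0.50 (0.0176), FBP, a fructose-1,6-bisphosphatase, by -0.64 (0.0104), and CAT1, catalase, by -0.48 (0.0271). Under quantile normalization these were -0.03, -0.08, -0.06, -0.11, -0.08, -0.56 and -0.07, with only FBP called (0.019), and the 584 brightest probe sets as a whole had a median of -0.35 as deposited and -0.06 after quantile normalization. In the paired fit only 1 of 22 rbcl probe sets was called, with 18 lower and 4 higher, from -1.304 to 0.625. For FBP and for CAT1, 1 of 2 probe sets was called in that fit. Over all alternatives the adjusted p ran from 0.000125 to 0.977 for PR5, from 0.00354 to 1 for xip, from 0.000953 to 0.995 for COMT1, from 0.00183 to 0.945 for WZF1 and from 6.38e-05 to 0.748 for lgul. For the photosynthesis genes and CAT1 the paired fit gave the smallest adjusted p of all, and the largest was 1. Without inoculated replicate 3 alone, nearly nothing was left of rbcl (0.03), PRK (0.03), PsbO (-0.02), PsbP (-0.04), petC (-0.01) and CAT1 (-0.01), and FBP stood at -0.24. Without mock replicate 3 alone, the same genes ran from -1.049 (rbcl) to -0.86 (CAT1). With all arrays of replicate 3 at 3 dpi left out they stood at -0.49, -0.42, -0.44, -0.43, -0.43, -0.38 and -0.58, none called. The photosynthesis genes, CAT1, PR5, xip and COMT1 were chosen after their values were seen.

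Of the fixed lists in TcLr34 at 3 dpi, the light harvesting list (PsbO and PsbP) had a median of -0.54, with an adjusted p of 0.182, or of 0.0166 with replicate pairs as blocks; adjusted p = 0.129 with an estimated correlation. The cold and abscisic acid list had 0 of 3 genes called (LEA1 0.59, Rab15 0.97, COR410 1.05; adjusted p = 0.182), and the peroxidase list 0 of 2, Prx1 at -0.75 and PER1 at -0.47 (0.182). The 3'/5' probe ratio of the sucrose synthase control was lower in the inoculated arrays by -0.50.

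In TcLr1 at 7 dpi, Ta_5248_1_S1_x_at, without a gene name, rose by 3.99 ± 0.45 (adjusted p = 5.04e-05; 0.0122 with replicate pairs as blocks), from 7.12 ± 1.13 to 11.11 ± 0.17 (SD, 3 arrays). It was also among those that rose in Tc at both times. DMAS1 (brightest probe set, 0.10) and PR5 (0.01) were not called. It was the only call by limma, which gave 1402 probe sets at an unadjusted p under 0.05, and the t-test gave 4 after adjustment. The paired fit called 3, adding unnamed Ta_4814_3_S1_at (2.14, 0.0214) and TaAffx_56618_1_A1_at (-1.55, 0.0284), and quantile normalization 1. Leaving out inoculated replicate 1, mock replicate 1 or mock replicate 3 gave 3, 4 and 2 calls, and none of the gene lists passed.

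In susceptible Tc at 7 dpi the response was large, and DMAS1, deoxymugineic acid synthase, rose by 2.37 ± 0.38 (Ta_5335_1_A1_x_at, adjusted p = 0.000412; 6.77e-06 with replicate pairs as blocks and 4.4e-08 to 0.0757 over all alternatives), from 10.76 ± 0.31 to 13.13 ± 0.22 (SD, 3 arrays). Its brightest probe set, Ta_5335_3_S1_a_at, differed by -0.08 and was not called. The glyoxalase gene lgul fell by 1.58 ± 0.31 (adjusted p = 0.00346), PEAMT1, a methyltransferase of choline synthesis, by 1.66 ± 0.42 (0.032), RPL9, named as ribosomal protein L9, by 1.68 ± 0.41 (0.0256) and Glu-D3, a glutenin of grain storage protein, by 1.78 ± 0.47 (0.0436). Over all alternatives the adjusted p reached 0.151, 0.21, 0.0908 and 0.329 for these 4 genes. The call of RPL9 was lost without any 1 of the 6 arrays (-1.73 to -1.64), those of PEAMT1 (-1.72 to -1.44) and Glu-D3 (-1.90 to -1.30) without any but inoculated replicate 2, and that of lgul without inoculated replicate 3 (-1.32). The largest changes were in unnamed TaAffx_66618_1_A1_at (8.09 ± 0.62), Ta_5248_2_S1_x_at (7.15 ± 0.52), Ta_22564_2_S1_x_at (-3.86 ± 1.02) and TaAffx_110154_1_S1_at (-3.56 ± 0.81). The calls of the last pair were lost without inoculated replicate 2 (-3.60 and -3.27), inoculated replicate 3 (-3.50 and -3.575), mock replicate 1 (-3.205 and -3.37) or mock replicate 3 (-3.64 and -3.57). In all, 607 probe sets rose and 384 fell. Of these, 605 and 381 did not overlap between treatments, as did 24.2% of all tested probe sets. That share was 7.71% in TcLr1 and 14.7% in TcLr34 at 7 dpi, and chance gives 10% only for exchangeable arrays without ties. The 3'/5' probe ratios of 2 controls differed between the treatments, G-6-PDH by -0.41 and ubiquitin by 0.129, each with an exact permutation p of 0.1, the smallest possible here.

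With replicate pairs as blocks, 2483 probe sets rose and 6276 fell in Tc at 7 dpi, against 1899 and 2140 under quantile normalization and 1515 and 1729 with 75th percentile scaling. The median of all tested probe sets was -0.13 as deposited and -0.03 after quantile normalization. In the paired fit Glc1 rose by 1.42 (paired adjusted p = 0.00205), WZF1 by 1.13 (0.00525), APRT, an adenine phosphoribosyltransferase, by 0.92 (0.000566) and the tubulin Tubb4 by 0.41 (0.0384). Lower in that fit were 6-FEH, a fructan exohydrolase, by -1.52 (0.00135; its brightest probe set -0.26), tubb2 by -1.21 (0.00591), Pgk-1, phosphoglycerate kinase, by -1.05 (0.000181), Prx1 by -0.98 (0.00025), AGA.1 by -0.92 (0.000648), the lipid transfer gene LTP3 by -0.88 (0.0031) and FBP by -0.73 (0.00269). The rbcl probe set TaAffx_128414_181_S1_at was lower by -0.98 (0.0203), while the brightest, Ta_24976_1_S1_x_at, was at -0.30, not called, and at 0.01 under quantile normalization. Over 22 rbcl probe sets, 17 lay lower and 5 higher, and 6 of the 22 were called in the paired fit. PsbP (-0.42, 0.0355), PRK (-0.42, 0.0281) and CAT1 (-0.46, 0.0214) were called only in the paired fit, and PsbO (-0.39, 0.088) and PR5 (-0.58, 0.0595) were not. Over all alternatives the adjusted p of Glc1 reached 0.334, WZF1 0.68, APRT 0.586, Pgk-1 0.504, Prx1 0.502, AGA.1 0.396 and 6-FEH 0.414. Glc1, WZF1, APRT, Pgk-1, Prx1 and AGA.1 also passed under quantile normalization without a block. None of the gene lists passed. Adjusted over the list alone, Prx1 was called lower, 1 of 2 peroxidases. Without inoculated replicate 3, or mock replicate 1, 2 or 3, the calls numbered 324, 645, 515 and 496.

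In TcLr34 at 7 dpi, Rab15 rose by 1.92 ± 0.35 (TaAffx_46097_2_S1_at, adjusted p = 0.0156; 0.00355 with replicate pairs as blocks and 0.000686 to 0.573 over all alternatives), from 9.56 ± 0.89 to 11.47 ± 0.57 (SD, 3 arrays), with its brightest probe set at 0.70, not called. The Rab15 call was lost without inoculated replicate 1 (1.66), inoculated replicate 2 (1.86) or mock replicate 3 (1.48). The largest changes were in unnamed Ta_20519_1_S1_at (4.06 ± 0.57), Ta_5861_2_S1_at (3.38 ± 0.33), Ta_3813_1_A1_at (-2.96 ± 0.54) and TaAffx_12211_1_A1_at (-2.79 ± 0.51). The call of Ta_3813_1_A1_at was lost without inoculated replicate 2 (-2.63) or 3 (-2.77) or mock replicate 1 (-2.89) or 2 (-2.87). That of TaAffx_12211_1_A1_at was lost without inoculated replicate 1 (-2.70) or 3 (-2.55) or mock replicate 1 (-2.26). In the paired fit at2G04570 rose by 2.28 (0.04; mock at the floor, brightest probe set -0.34) and WZF1 by 1.06 (0.0295), and PEAMT1 (-0.81, 0.0227), Prx1 (-0.72, 0.0342; brightest -0.47), Trx-M, an m-type thioredoxin (-0.60, 0.0239), AdSS, adenylosuccinate synthetase (-0.59, 0.0145), and PsbP (-0.53, 0.0439; brightest -0.38) were lower. The sucrose synthase 3'/5' ratio was lower in the inoculated arrays by -0.63 and the polyadenylated spike controls by -0.32, each with an exact permutation p of 0.1, the smallest possible here. In all, 65 probe sets rose and 8 fell, against 780 and 1393 with replicate pairs as blocks and 259 and 61 under quantile normalization. Leaving out inoculated replicates 1, 2 and 3 or mock replicates 2 and 3 gave 20, 25, 21, 32 and 39 calls, and none of the gene lists passed.

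**Figure D2:**
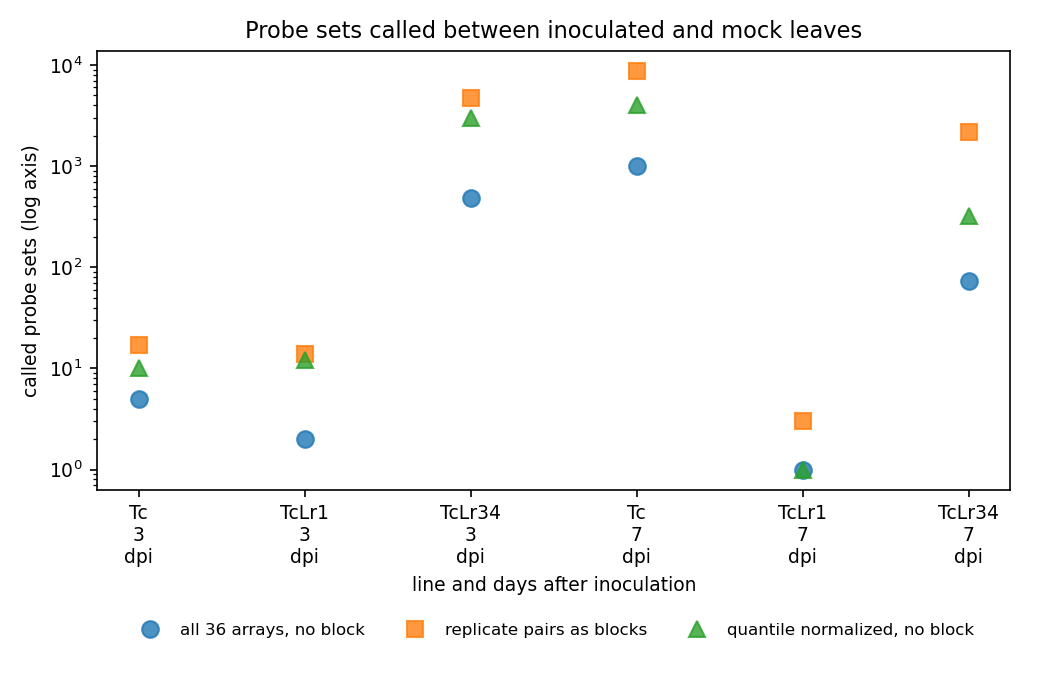
Number of probe sets called between inoculated and mock leaves (vertical, log axis) in each line and time (horizontal), without a block (circles), with replicate pairs as blocks (squares) and after quantile normalization without a block (triangles). TcLr34 at 3 dpi (487, 4732 and 2971) and Tc at 7 dpi (991, 8759 and 4039) have the most calls.

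Of the 5 fixed lists with at least 2 tested genes, none passed in any response without a block, with all arrays and 1 probe set per gene. With replicate pairs as blocks, light harvesting passed in TcLr34 at 3 dpi (adjusted p = 0.0166). The adjusted p-values that follow are without a block unless stated. The cold and abscisic acid genes LEA1, Rab15 and COR410 had medians of 0.97 and 0.31 in TcLr34 at 3 and 7 dpi (adjusted p = 0.182 and 0.508), and 1.23e-06 and 0.00427 when every probe set of a gene was used. In that setting the probe sets of a gene (3 for Rab15) enter as separate members at the preset correlation of 0.01. A gene then counts more than once, so adjusted p-values with every probe set can be too small. The peroxidases (Prx1 and PER1) had a median of -0.50 in TcLr1 at 3 dpi (0.393; 0.0244 with every probe set). The histones H2A-2, H2A-3 and H2A-9 had -0.31 in TcLr34 at 3 dpi (0.234; 0.0303 with every probe set), where the peroxidase and light harvesting lists also passed with every probe set (0.00333 and 0.0341), and the chaperones FKBP70 and hsp16.9A had 0.57 (0.234). In the other responses the adjusted p was 0.78 in Tc at 3 dpi, 0.86 for the other lists of TcLr1 at 3 dpi, 0.708 to 0.988 in Tc at 7 dpi, 0.908 in TcLr1 at 7 dpi and 0.508 to 0.618 in TcLr34 at 7 dpi. For the cold and abscisic acid list the median was positive and the mean negative in TcLr1 at 3 dpi (0.03 and -0.08) and at 7 dpi (0.14 and -0.10), and the chaperones of Tc at 7 dpi had a median of -0.07 with a test directed upward. Among extended lists, the Calvin cycle (rbcl, PRK and FBP) passed in TcLr34 at 3 dpi with replicate pairs as blocks (0.00261; 0.17 with an estimated correlation) and not without them (0.253), and so did light harvesting (0.0166; 0.171; 0.253). Other fixed lists had a single tested gene each, GSTZ1, a glutathione transferase, PR5, COMT1, rbcl or Serpin-Z2A, a grain protease inhibitor, and were not tested.

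Set against the response of Tc, the response of TcLr34 at 3 dpi was higher for Rab15 by 3.76 ± 0.49 (adjusted p = 0.000537, or 0.000771 with replicate pairs as blocks, and 3.27e-05 to 0.309 over all alternatives, with the brightest probe set at 0.86, not called). Here both Tc groups and the TcLr34 mock leaves were at the floor with an SD of 0, so this error can be too small. The TcLr34 response was also higher for unnamed Ta_5861_2_S1_x_at (3.43), Ta_18678_1_S1_at (2.92), Ta_5861_2_S1_at (2.92) and Ta_9552_2_S1_at (2.49). With Rab15 these were all 5 calls, named after their values were seen. With replicate pairs as blocks 497 were higher, WZF1 (1.61) among them, and 90 lower, including lgul (-1.19) and Prx1 (-0.87); under quantile normalization 269 were higher and 46 lower. Leaving out TcLr34 mock replicate 3 gave 8 calls and Tc mock replicate 3 gave 115. TcLr1 at 3 dpi differed from Tc in 0 probe sets by limma, with 926 at an unadjusted p under 0.05, and in 1 with replicate pairs as blocks.

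At 7 dpi, DMAS1 responded less in TcLr1 than in Tc, by -2.43 ± 0.54 (adjusted p = 0.0403; 0.0004 with replicate pairs as blocks; 4.58e-05 to 0.142 over all alternatives; brightest probe set 0.18), and in TcLr34 by -2.28 ± 0.54 (0.0627; 0.000693; 9.55e-05 to 0.199). The TcLr1 call was lost without any 1 of the 12 arrays (-2.57 to -2.26). Rab15 responded more in TcLr34 than in Tc, by 2.19 ± 0.49 (0.0429; 0.00807; 0.00451 to 0.606; brightest 0.70), a call lost without 10 of the 12 arrays (1.76 to 2.33), all but TcLr34 inoculated replicate 3 and mock replicate 2. With replicate pairs as blocks, RPL9 (1.69), PEAMT1 (1.65), lgul (1.34), Pgk-1 (0.93), Prx1 (0.86) and AGA.1 (0.81) stood higher in the TcLr1 response and Glc1 (-1.62), the histone H2A-9 (-1.49; brightest probe set 0.36) and APRT (-0.88) lower. In the TcLr34 response rbcl (2.06; brightest -0.10), RPL9 (1.15) and lgul (1.02; brightest 0.98) were higher, and H2A-3 (-1.31; brightest 0.60) and APRT (-1.16) lower, in that fit. The largest differences in unnamed probe sets were Ta_188_1_S1_at (-7.13) and TaAffx_55269_1_S1_s_at (4.81) for TcLr1 and TaAffx_66618_1_A1_at (-7.28) and Ta_20519_1_S1_at (6.59) for TcLr34. In all, the TcLr1 response was higher in 27 and lower in 119 probe sets (2642 and 1052 paired; 430 and 624 quantile; 236 and 417 with 75th percentile scaling), and that of TcLr34 in 57 and 95 (588 and 493 paired; 215 and 283 quantile). For TcLr1 the calls numbered 94 without its inoculated replicate 2, 86 without its mock replicate 1 and 79 without Tc inoculated replicate 3; for TcLr34 they numbered 93 and 78 without inoculated replicate 3 of TcLr34 and of Tc.

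From 3 to 7 dpi the Tc response increased for unnamed TaAffx_66618_1_A1_at (6.01 ± 0.87) and Ta_23970_1_A1_x_at (5.42 ± 0.75) and decreased for TaAffx_2547_1_S1_at (-4.28 ± 0.56) and Ta_20519_1_S1_at (-4.06 ± 0.80), with 66 higher and 8 lower. With replicate pairs as blocks the counts were 727 and 2493, with DMAS1 (1.93; brightest -0.39), WZF1 (1.44) and APRT (0.80) higher and lgul (-1.60), RPL9 (-1.58), PEAMT1 (-1.46), rbcl (-1.12; brightest -0.25; -0.39 without 3 dpi mock replicate 3), Prx1 (-1.10) and AGA.1 (-1.05) lower. Scaling moved the split to 308 and 166 (quantile) or 218 and 105 (75th percentile), and the median of all probe sets was -0.18 as deposited (-0.15 in TcLr34, and 0.13 for the TcLr1 response against that of Tc at 7 dpi). Leaving out 3 dpi inoculated replicate 1, 3 dpi mock replicate 2 or 7 dpi inoculated replicate 3 gave 48, 36 and 38. In TcLr34, Ta_23673_1_S1_a_at (3.35) and Ta_5151_1_S1_x_at (2.12) were higher at 7 dpi and Ta_18678_1_S1_at (-2.80) and Ta_9552_2_S1_at (-2.47) lower, its 4 calls. The paired fit gave 24 and 357 with Rab15 at -1.85 (paired adjusted p = 0.0409), quantile normalization 6 and 81, and 75th percentile scaling 3 and 12. Leaving out 1 array gave 1 call (3 dpi inoculated replicate 1 or mock replicate 2) or 2 calls (3 dpi mock replicate 1, 7 dpi inoculated replicate 2 or 7 dpi mock replicate 1). In TcLr1, Ta_5248_1_S1_x_at (3.99, adjusted p = 0.0384) was the 1 call, with 0 in the paired fit and, under quantile normalization, 2 higher and 1 lower; it was lost without any 1 of 9 arrays, and 2 calls were made without 3 dpi inoculated replicate 3 or 7 dpi mock replicate 1.

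Among mock leaves of both times (6 arrays of a line), LEA1, a late embryogenesis abundant protein, was higher in TcLr34 than in Tc by 5.16 ± 0.39 (adjusted p = 2.96e-10; 3.06e-14 to 5.29e-06 over all alternatives), and Rab15 by 1.55 ± 0.40 (Ta_2704_1_S1_x_at, 0.0308; 0.00417 to 0.14). LEA1 stood at 12.37 ± 0.70 and 13.32 ± 0.44 (SD, 3 arrays) in TcLr34 mock leaves at 3 and 7 dpi, against 8.15 ± 0.36 and 7.23 ± 0.81 in Tc. The Rab15 call was lost without 7 of the 12 arrays: Tc 3 dpi replicates 1 (1.23) and 2 (1.55), Tc 7 dpi replicate 1 (1.23), TcLr34 3 dpi replicates 2 (1.51) and 3 (1.55), and TcLr34 7 dpi replicates 1 (1.50) and 2 (1.54). The largest differences were in unnamed Ta_2638_1_S1_at (7.09 ± 0.44), Ta_9389_1_S1_at (5.86 ± 0.77), Ta_4137_1_S1_at (-7.98 ± 0.29) and Ta_28123_1_S1_at (-7.67 ± 0.29). In all, 603 were higher and 509 lower, or 952 and 937 with the replicate number as a block. The larger share turned to lower under quantile normalization (1192 and 1332), with the replicate block by day (1747 and 2130) and with replicate 3 at 3 dpi left out (951 and 1301). Of 529 called from the 3 dpi arrays only, 88.7% had a difference in the same direction at 7 dpi, and 171 were also called there. TcLr1 mock leaves differed from Tc in 45 higher and 22 lower probe sets, or 68 and 27 with the block and 56 and 42 under quantile normalization. Its largest differences were in unnamed TaAffx_109711_1_S1_at (6.84 ± 0.41), Ta_21783_1_S1_at (6.60 ± 0.27), Ta_8254_1_A1_at (-6.0 ± 0.63) and Ta_10194_1_S1_at (-4.72 ± 0.58).

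**Figure D3:**
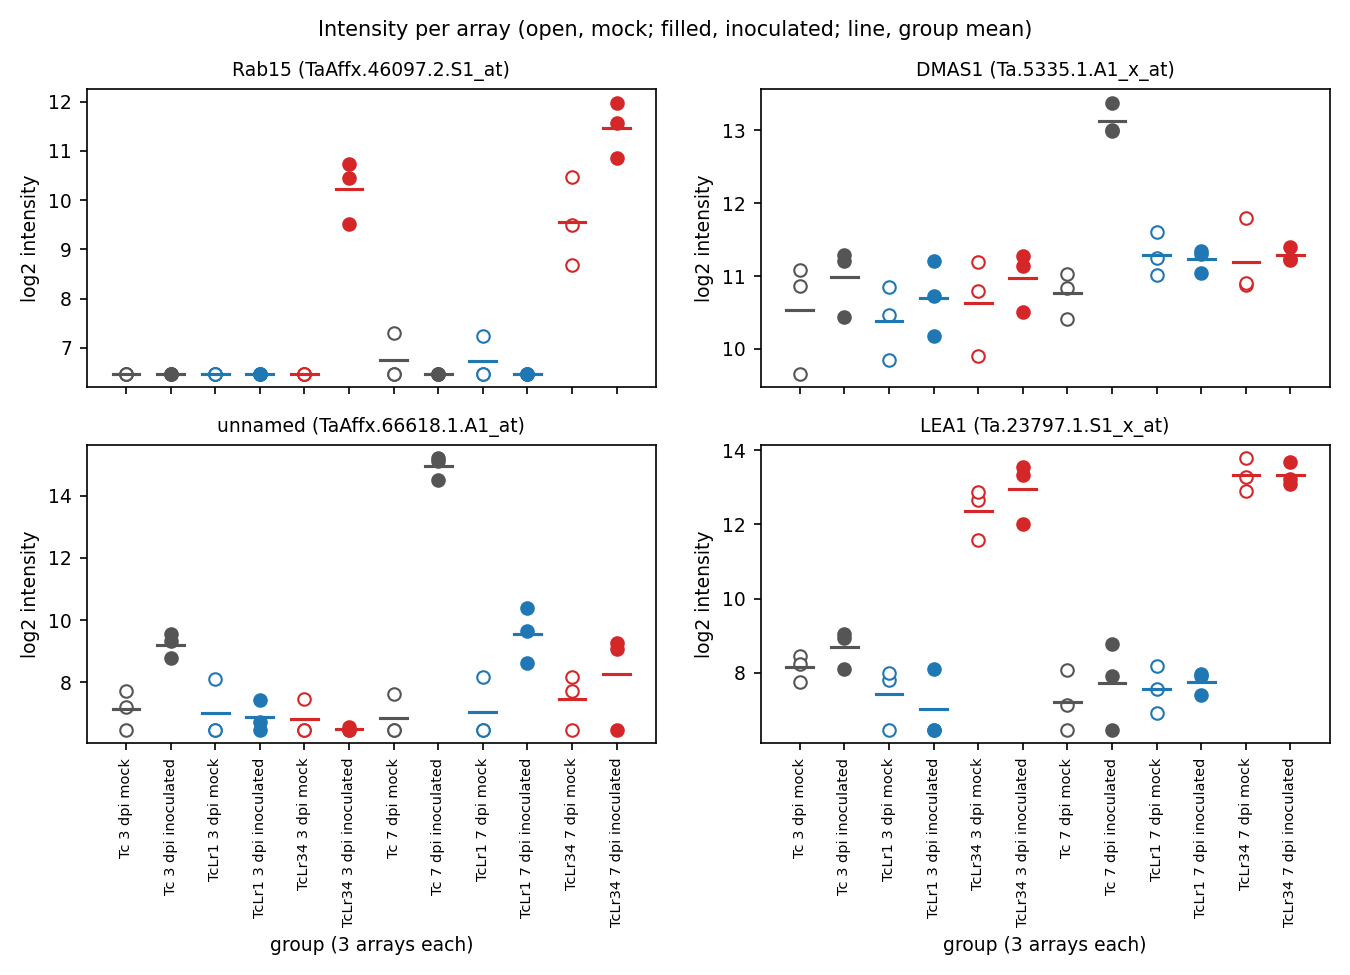
Log2 intensity (vertical) of 4 probe sets in every array, by group (horizontal), with open symbols for mock, filled symbols for inoculated and lines at the mean of 3 arrays. Rab15 is at the floor of 6.47 in all mock arrays of TcLr34 at 3 dpi, DMAS1 averages 13.13 in inoculated Tc at 7 dpi, TaAffx_66618_1_A1_at averages 14.95 there, and LEA1 is highest in the 12 arrays of TcLr34.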

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

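The scaling test of abundant transcripts, both tests of probe sets dark in mock leaves, the count of splits by the place of replicate 3 and the splits of the paired fit were chosen only after the results were seen.

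Responses differed between lines or times by tests of the difference itself. These gave 5 calls for TcLr34 against Tc at 3 dpi, 146 for TcLr1 against Tc at 7 dpi, 152 for TcLr34 against Tc at 7 dpi, and, for 7 against 3 dpi, 74 in Tc, 1 in TcLr1 and 4 in TcLr34. Among named genes, which were not put to splits, the differences were 3.76 for Rab15 in TcLr34 against Tc at 3 dpi, 2.19 for Rab15 at 7 dpi and -2.43 for DMAS1 in TcLr1 against Tc at 7 dpi. In 100 drawn splits of the same arrays (of 200 possible), chance could not be excluded for any of these 6 counts of calls of the fit without a block: the highest other split gave 11385, 230, 884, 303, 5 and 174 calls in the order above, and 10, 12, 7, 5, 25 and 12 splits gave as many as the real one. Among splits that part as many pairs the highest other was 114, 192, 884, 182, 5 and 159. For TcLr1 against Tc at 3 dpi the real split gave 0 and the highest other 14098, with 0 among splits that part as many pairs and 100 of 100 splits as large. Splits with many more calls at 3 dpi (11385 and 14098) point to a structure of the samples. For TcLr1 against Tc, the 9 splits in which the 4 arrays of replicate 3 pull the difference the same way gave 6 to 14098 calls (median 9755), and every other drawn split gave at most 1. For TcLr34 against Tc, 9 such splits gave 0 to 11385 (median 2), and the others up to 530, so the place of these arrays does not account for every count there.

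The same 6 counts with replicate pairs as blocks were 587, 3694, 1081, 3220, 0 and 381. Exchanging the treatments within pairs makes 32 splits. The highest other split gave 2867, 3480, 9940, 4293, 25 and 6141, and 5, 1, 5, 5, 32 and 6 splits gave as many. For TcLr1 against Tc at 7 dpi the share of 0.0312 is the smallest that 32 splits allow. There the splits that keep the Tc pairs in 1 direction gave 2989 to 3694 calls, the real one among them. Splits that break up the Tc pairs gave 0 or 1. The splits thus follow the Tc response and are no test of a difference between the lines. Chance was not excluded for the other counts. TcLr1 against Tc at 3 dpi had 1 call, and the highest other split had 154. In each of these the highest other split was the one that reverses 1 response as a whole and so tests the sum of both responses. Without it the highest was 1969, 3457, 5385, 3905, 2 and 1624. The counts of 1624 or more came from splits that keep 1 response whole or reverse it as a whole. Splits that break up both responses gave 0 to 2 calls. In the fit without a block the 884 of TcLr34 against Tc at 7 dpi came from that split too, with 252 next. A high count in a split that keeps or reverses 1 response as a whole holds real responses and is not what chance alone gives.

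For the 6 responses the 10 possible splits are too few to judge chance. The real and highest other counts were 5 and 0 (Tc, 3 dpi), 2 and 2 (TcLr1, 3 dpi), 487 and 3 (TcLr34, 3 dpi), 991 and 6 (Tc, 7 dpi), 1 and 2 (TcLr1, 7 dpi), and 73 and 2 (TcLr34, 7 dpi). For the gene lists the real count was 0 in every response and the highest other 1, 1, 0, 2, 0 and 0. For mock TcLr34 against Tc the real split gave the most calls of 100 drawn (1112, highest other 750). So it did for mock TcLr1 against Tc (67, highest other 2). Among the 20 and 13 splits that part as many pairs, the highest others were 312 and 2. These splits relabel the arrays of 3 and 7 dpi separately. Arrays of a line and replicate may share a main plot at both times, which would leave far fewer splits. Chance is therefore excluded for these 2 counts only if the times are independent.

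Abundant transcripts were lower after inoculation where many probe sets were called. The 584 brightest probe sets had medians of -0.35 in TcLr34 at 3 dpi, -0.42 in Tc at 7 dpi and -0.36 in TcLr34 at 7 dpi, which quantile normalization moved to no lower than -0.0717, so scaling of the arrays is a candidate explanation. The photosynthesis genes (rbcl, PsbO, PsbP, PRK and FBP) lay at percentile 13.7 of 10000 random lists of like abundance in TcLr34 at 3 dpi, inside the range set for abundance alone. The random lists left out only the probe sets of these 5 genes. As 60017 probe sets have no symbol, other photosynthesis genes may be among the lists, so the test cannot tell photosynthesis from abundance. A true loss of abundant leaf transcripts stays open, since quantile normalization would remove it too.

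The mock leaves of TcLr34 differed from those of Tc. Of 529 calls at 3 dpi, 88.7% had the same direction at 7 dpi and 171 were also called there (6.8 expected), with r = 0.244 across probe sets. The 6.8 takes the calls as independent, though both days share the residual SD of each probe set. All 171 had the same direction at both times. The shared direction argues against a difference between arrays of 1 day as the whole account, though most 3 dpi calls were not called at 7 dpi. Scaling is argued against too, since 97.8% of the calls stayed in the same direction under quantile normalization. An effect of the introgressed segment may account for the difference between mock leaves, as may other differences between the lines, which the design does not separate.

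Some probe sets were dark in mock leaves and bright in inoculated Tc at 7 dpi. Of 245 tested probe sets below the detection filter in all 18 mock arrays, 32 were called higher there. Of all 48979 tested probe sets, 607 were called higher in Tc at 7 dpi. The 245 were tested only because at least 3 inoculated arrays exceeded the filter, which by itself raises the share called higher. To weigh noise near the floor, all 8434 probe sets below the filter in the mock arrays were used, tested or not. Of those that exceeded the filter in 1 inoculated Tc 7 dpi array (153, 207 and 435 for replicates 1, 2 and 3), 28 also exceeded it in both others, where arrays independent of each other would give 0.194 and the highest other pair of inoculated arrays gave 9, 8 and 9. This argues against noise that differs from array to array. The definition first used, at the floor in every mock array, had left 1 probe set, also called, and was replaced by the detection filter after that result was seen. RNA of the fungus may account for them, as may plant transcripts switched on by infection. The median response of these 32 in TcLr1 at 7 dpi was 0.283, and these cannot be told apart because no fungal annotation of the probes was used.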

How the results depend on the processing

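The replicate block by day, the omission of replicate 3 at 3 dpi, quantile normalization with the paired block and the omission of reporter probe sets were tests chosen only after the data were seen. Counts of calls are given in the order of lines Tc, TcLr1, TcLr34 unless stated. The causes of these changes were not tested, except that limma on fewer arrays has fewer degrees of freedom. Signal over background limits what probe sets near the floor can show, and 3 arrays per group limit the precision.

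Paired replicate block within line and day: 17, 14 and 4732 at 3 dpi; 8759, 3 and 2173 at 7 dpi; TcLr1 and TcLr34 against Tc, 1 and 587 at 3 dpi and 3694 and 1081 at 7 dpi; 7 against 3 dpi, 3220, 0 and 381; 1 gene list in TcLr34 at 3 dpi. Of the extended lists, light harvesting and the Calvin cycle passed there in that fit, and neither with an estimated correlation (adjusted p = 0.171 and 0.17).

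Replicate number as a block: 4 (TcLr1) and 1300 (TcLr34) at 3 dpi; 3605 (Tc) and 185 (TcLr34) at 7 dpi; TcLr1 and TcLr34 against Tc, 1 and 30 at 3 dpi and 595 and 301 at 7 dpi; 7 against 3 dpi, 329 (Tc) and 8 (TcLr34); mock TcLr34, 1889. Replicate block by day: 19, 38 and 4586 at 3 dpi; 8690 (Tc) and 2018 (TcLr34) at 7 dpi; against Tc, 1 and 566 at 3 dpi and 3704 and 1167 at 7 dpi; 7 against 3 dpi, 3286, 0 and 453; mock TcLr1 139 and mock TcLr34 3877; 1 gene list in TcLr34 at 3 dpi.

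Quantile normalization: 10, 12 and 2971 at 3 dpi; 4039 (Tc) and 320 (TcLr34) at 7 dpi; TcLr34 against Tc at 3 dpi, 315; TcLr1 and TcLr34 against Tc at 7 dpi, 1054 and 498; 7 against 3 dpi, 474, 3 and 87; mock TcLr34, 2524. With the paired block as well: 17, 29 and 5833 at 3 dpi; 7936, 2 and 1139 at 7 dpi; against Tc, 1 and 1028 at 3 dpi and 2995 and 1338 at 7 dpi; 7 against 3 dpi, 1902, 0 and 237. Scaling to the 75th percentile: 4 (TcLr1) and 1839 (TcLr34) at 3 dpi; 3244 (Tc) and 306 (TcLr34) at 7 dpi; against Tc, 87 (TcLr34, 3 dpi), 653 and 343 (7 dpi); 7 against 3 dpi, 323 (Tc) and 15 (TcLr34); mock TcLr34, 2127.

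Floor at the 40th percentile: 0 (TcLr1) and 771 (TcLr34) at 3 dpi; 1606, 3 and 242 at 7 dpi; against Tc, 1 and 20 at 3 dpi and 355 and 328 at 7 dpi; 7 against 3 dpi, 270 (Tc) and 13 (TcLr34). No floor: 3 (Tc, 3 dpi), 2 (TcLr34 against Tc, 3 dpi) and, 7 against 3 dpi, 47, 0 and 2. No filter: 3 (Tc) and 4 (TcLr1) at 3 dpi and 4 for 7 against 3 dpi in TcLr1. Stricter filter: 8 (Tc) and 1 (TcLr1) at 3 dpi, 4 (TcLr1, 7 dpi), 9 (TcLr34 against Tc, 3 dpi) and 2 (7 against 3 dpi, TcLr1).

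limma on the 6 arrays alone: 0, 0 and 25 at 3 dpi; 294, 0 and 0 at 7 dpi. The methods' t-test at an unadjusted p under 0.05: 1072, 1038 and 3040 at 3 dpi; 7832, 1857 and 3959 at 7 dpi; after adjustment 0 (Tc, 3 dpi), 1 (TcLr34, 3 dpi), 110, 4 and 3 (7 dpi). Replicate 3 at 3 dpi left out: 1, 1 and 835 at 3 dpi; TcLr34 against Tc, 153; 7 against 3 dpi, 248 (Tc) and 94 (TcLr34); mock TcLr34, 2252; 1 gene list in TcLr1 at 3 dpi. Every probe set of a gene in the lists, where a gene can count more than once: 1 (TcLr1, 3 dpi), 4 (TcLr34, 3 dpi) and 1 (TcLr34, 7 dpi) lists passed.

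Leaving out 1 array gave 3 to 4, 1 to 3 and 220 to 396 calls at 3 dpi and 324 to 792, 1 to 4 and 20 to 54 at 7 dpi. Against Tc it gave 0 to 0 (TcLr1) and 4 to 115 (TcLr34) at 3 dpi and 79 to 144 and 78 to 153 at 7 dpi; for 7 against 3 dpi 36 to 86, 0 to 2 and 1 to 5; for mock leaves 49 to 65 (TcLr1) and 820 to 1278 (TcLr34); and 0 to 0 gene lists in each response.

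Reversed were PRK (0.0261, range -0.943 to 0.0261) and rbcl (0.0252, range -1.049 to 0.0252) in TcLr34 at 3 dpi without inoculated replicate 3, the lowest values being without mock replicate 3, rbcl in Tc at 7 dpi under quantile normalization with or without the paired block (0.00736), and TaAffx_56618_1_A1_at in TcLr1 at 7 dpi with the floor at the 40th percentile (0, where all its values lie at the floor). Of the named results, 104 of 104 kept direction and call without the reporter probe sets. Under quantile normalization 80 of 104 kept both, 23 gained a call, 0 lost it and 1 reversed. The call was lost in 16 of 71 by limma on the 6 arrays alone and in 21 of 71 by the adjusted t-test. In all these counts, also with 1 array left out, a result called neither in the main fit nor in the alternative counts as kept. Many named results were not called in the main fit, so the losses are a larger share of those that had a call to lose. Many of the named results were chosen from calls of the paired fit, so no such count is given for it. Leaving out 1 array kept 744 of 822, lost the call in 75, gained it in 1 and reversed 2.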

Other observations

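All tests of this part were planned except the overlaps of calls between responses, chosen only after the results were seen.

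Responses that share no arrays overlapped. They come from 1 fit, however, with 1 residual SD for each probe set, so a probe set with a small SD is more easily called in several responses. The numbers expected for independent lists leave this out, so overlaps above them need not mean a shared response. Of the probe sets higher in TcLr34 at 3 dpi, 34 were also higher in TcLr34 at 7 dpi, Rab15 among them, where independent lists would share 0.603 (486 and 51.3 with replicate pairs as blocks). A further 42 were higher both in TcLr34 at 3 dpi and in Tc at 7 dpi (5.63 expected), 6 were lower in both (0.259 expected), and 17 had opposite directions (3.97 expected). In the paired fit (replicate pairs as blocks) these counts were 686 (163 expected), 1049 (194 expected) and 352 (489 expected), so opposite directions went from above to below the number expected, and lower in both outnumbered higher in both. Higher calls of Tc and TcLr34 at 7 dpi shared 8 (0.806 expected), 1 was lower in both (0.0627 expected), and 3 had opposite directions (0.609 expected). The paired fit gave 202 (39.5 expected), 914 (178 expected) and 95 (171 expected), with the same changes. Rab15 was at 9.56 ± 0.89 (SD, n = 3) in TcLr34 mock leaves at 7 dpi and at the floor of 6.47 in all 3 at 3 dpi, so its level differed between times without inoculation, a difference that was not tested.

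The response of Tc at 7 dpi was set against the difference of TcLr34 from Tc in mock leaves of 3 dpi, which share no arrays. Across probe sets, which are not independent replicates, r was 0.0961 as deposited and 0.0666 under quantile normalization, between the bounds set for and against scaling of the arrays as the explanation, so the test did not decide. Called in both were 40 higher (1.75 expected), 9 lower (3.04 expected) and 12 in opposite directions (5.91 expected). Here too the numbers expected leave out that both comparisons share the residual SD of each probe set.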
